A study of Mus musculus with 3 samples.

How the data were processed

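Gene expression was measured in 3 mouse bone marrow cultures of the C57/BL6 strain on 3 Affymetrix arrays, 1 array per time. Per the labels, bone marrow cells were grown for 3 days with human M-CSF at 50 ng/ml, a cytokine that drives macrophage growth, and the resulting macrophages were then given human RANKL at 150 ng/ml for 0, 24 or 72 h. RANKL is the cytokine that turns macrophage precursors into osteoclasts, the multinucleated cells that resorb bone. Per the labels, total RNA was extracted with a spin column kit and 5 µg of it was turned into biotin-labelled cRNA.

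The deposited values are microarray intensity signals on a linear scale, 1 per probe set and array, and the submitters' processing notes name MAS5 as the software that made them, with the version not given in the sources used here. The table held 22690 probe sets, of which 64 are control probe sets, leaving 22626 probe sets for genes. Gene names came from the platform annotation of 2016. It gave 1 gene symbol for 20380 probe sets, several for 691 and none for 1555; probe sets with several symbols or none named no gene. Of the 20380 single-symbol probe sets, 20351 matched a mouse reference gene by identifier and 0 of their symbols needed updating. For names only, the reference assembly was GRCm38.p6, and no coordinates are given because the sources used here name no genome build. These probe sets covered 12393 genes.

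The deposited arrays were not on a common scale. The median signal over gene probe sets was 36.7 at 0 h, 60.9 at 24 h and 62.7 at 72 h. The analysis had been planned on the deposited scale, under the assumption that the arrays had been brought to a common scale. Because the median log2 signal lay 0.73 higher at 24 h and 0.77 higher at 72 h than at 0 h, every change below is instead given relative to the median of all gene probe sets, by centring the log2 values of each array on that median. Scaled signals are on the mean scale of the 3 arrays. This median centring had been listed as an alternative before the data were examined. The deposited scale is now reported as an alternative, as are scaling to the 18 hybridization control probe sets and scaling to a 2% trimmed mean, and these 3 were chosen after seeing the data.

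Scaled values under a floor, the 40th percentile of all gene probe sets pooled over the arrays (29.6 signal units, 4.89 on the log2 scale), were set to it. A gene was represented by its single-symbol probe set with the highest mean log2 value over the 3 arrays. It counted as measured in a comparison when at least 1 of the 2 arrays was above the floor. A gene was called higher or lower when its log2 difference reached 1 (2-fold). Where 1 side was at the floor the fold is a lower bound, written "at least", and where both were, no fold is given.

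With 1 array per time there is no replicate error, no test and no p-value, and the number of arrays limits the precision. The error given is technical. It is the SD over genes of the difference between 2 probe sets of the same gene, both above the floor, divided by the square root of 2. It came to 0.41 on the log2 scale for 24 h against 0 h (2727 genes), 0.49 for 72 h against 0 h (2702 genes) and 0.36 for 72 h against 24 h (2785 genes), or factors of 1.33, 1.41 and 1.28. It leaves out the variation between cultures. Among dimmer genes it was larger, 0.45 against 0.36 in the brighter genes for 24 h against 0 h.

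Before the data were examined, 32 gene lists were fixed: resorption machinery, cell fusion, osteoclast transcription factors, negative regulators of osteoclast differentiation, RANK and M-CSF signalling with its co-receptors, V-ATPase subunits, lysosomal hydrolases and membrane proteins, oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, cell cycle, cyclin-dependent kinase inhibitors with G1 cyclins, interferon-stimulated genes, MHC class II antigen presentation, macrophage markers, inflammatory cytokines and chemokines, cholesterol synthesis, iron handling, osteoclast-derived coupling factors, actin ring and podosome, housekeeping genes, ribosomal proteins, and markers of neutrophils with their precursors, B cells, T and NK cells, erythroid cells, mast cells with basophils, megakaryocytes with platelets, stromal cells with osteoblasts, endothelial cells, dendritic cells and adipocytes. For each list with at least 3 measured genes, the median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean log2 signal in 20 bins. This percentile describes these 3 arrays and is not a p-value. A list is said to stand apart at or beyond the 2.5 or 97.5 percentile. With 32 lists in 3 comparisons, 90 list values were obtained and 42 stood apart.

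Named genes followed a rule fixed before the data were examined. It takes the largest changes among genes above the floor on both arrays (8 each way for 72 h against 0 h, 6 for 24 h against 0 h, 5 for 72 h against 24 h), and the brightest genes at the floor on 1 array and at least 4 times the floor on the other (4, 3 and 2 each way). For both, the gene needed a proper name and every other measured probe set of it had to change in the same direction. The rule also takes, from each list, up to 4 members with the largest change and up to 2 within 2-fold, and 13 osteoclast genes named in advance that had a single-gene probe set. Dcstamp and Atp6v0d2 had none and were not analysed here. Outside this rule, Cd68 and Dcn at 72 h against 0 h were named because they went against their lists, Lum of the stromal list was named in the closing section for the same reason, and genes of lists added later, used in the closing section, were named as examples or counter-examples.

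Alternatives changed 1 choice at a time: the floor at the 20th or 60th percentile or none (values under 1 set to 1), quantile normalization and the other scalings above, the mean over the probe sets of a gene, leaving out probe sets whose name endings (_a_at, _s_at, _x_at) mark several transcripts of 1 gene or possible binding of other genes, called multi-transcript probe sets here, fold thresholds of 1.5 and 3, and random lists without matching. Comparison values for counts and overlaps came from 100 simulated sets of 3 unchanged arrays with the probe set error, the same for all genes. They leave out variation between cultures and error shared by the probe sets of a gene, so they give no rate of false calls. The calculation was tested on simulated arrays for 72 h against 0 h over 12393 genes, 200 of them changed. It called 89.7% of the 68 genes changed by 1.5 on the log2 scale, 98.5% of the 66 changed by 2 and 100% of the 66 changed by 3, and 134 of 7967 measured unchanged genes. The changed genes were all drawn from bright genes far above the floor, so these shares do not cover genes near it. Of 200 unshifted random lists, 9 fell beyond the 2.5 or 97.5 percentile. Their genes had independent simulated error, so this does not cover lists whose genes move together. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.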

Results

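To follow the change in gene expression as macrophages become osteoclasts, transcript signals were compared among 3 mouse bone marrow cultures. All had been grown with M-CSF for 3 days, and they were harvested after 0, 24 or 72 h of RANKL, with 1 array each. There were no replicates, so the differences below have no replicate check, and the technical error between probe sets of a gene (a factor of 1.33 to 1.41 against 0 h) is the only error at hand. No culture was kept for 24 or 72 h without RANKL, so the effects of RANKL and of further time in culture cannot be told apart. Of 12393 genes, 7990 were above the floor at 0 h, 7904 at 24 h and 7913 at 72 h. Log2 signals correlated across genes with r = 0.92 between 0 and 24 h, 0.89 between 0 and 72 h and 0.94 between 24 and 72 h, where genes are not independent replicates. Relative to 0 h, the deposited values were shifted upward by a median of 0.73 at 24 h and 0.77 at 72 h on the log2 scale, and all changes are given relative to that shift.

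After 24 h of RANKL, the cultures had higher signals of early osteoclast regulators, cell cycle genes and mitochondrial enzymes, and lower signals of most macrophage markers. Jdp2, an AP-1 family transcription factor, was 12.5-fold higher by its brightest probe set, Myc was 6.71-fold higher, and Nfatc1, the master transcription factor of osteoclast formation, rose 4.74-fold from a signal of 368 to 1742. Irf8, a repressor of osteoclast formation, was 6.62-fold lower. By the 2-fold rule 1112 genes were higher and 778 lower among 8439 measured, and unchanged arrays with the probe set error gave 64.0 and 63.9 on average. That simulation leaves out variation between cultures, so it gives no rate of false calls. The split of higher and lower calls depended on the scaling. With 58.8% of the calls higher in the main setting, the share was 46.9% after quantile normalization, 42.2% after trimmed mean scaling and 91.3% on the deposited scale (3302 higher and 314 lower).

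The largest increases at 24 h among genes above the floor on both arrays were those of Cav1 (23.9-fold), the caveolin of plasma membrane pits, Slc6a4 (18.6-fold), the serotonin transporter, Tufm (16.3-fold), a mitochondrial elongation factor, Cyp2s1 (15.9-fold), Sdc1 (13.7-fold), a cell surface proteoglycan, and Scin (13.6-fold), an actin-severing protein. The Tufm value rests on 1 probe set with a 0 h signal just above the floor, since its others were at the floor, and its call was lost when probe sets were averaged. From the floor, Pcdh7 was at least 28.7-fold higher, Ocstamp, a membrane protein needed for osteoclast fusion, at least 10.7-fold, and Vegfc had a log2 difference of at least 3.32. The largest decreases were those of Ikbke (30.5-fold), a kinase of innate immune signalling, Gas6 (22.9-fold), Mrc1 (21.4-fold), the mannose receptor, Fcrls (19.7-fold), Rnase4 (17.5-fold) and the noncoding RNA Malat1 (16.8-fold), whose call was lost without multi-transcript probe sets. Cbr2, Marco and Atf3 dropped to the floor, at least 17.3-fold, 10.4-fold and 9.80-fold lower.

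Of the osteoclast lists, those of resorption and transcription factors were high by 24 h. In the resorption list, genes for dissolving bone, 7 of 13 measured members were at least 2-fold higher and 0 lower, with a median log2 difference of 1.07 (percentile 99.97). Car2, the carbonic anhydrase that supplies acid, was 6.93-fold higher, Ctsk, the collagen-degrading cathepsin, 5.21-fold, Src 4.35-fold and Acp5, the tartrate-resistant acid phosphatase, 4.32-fold. Calcr, the calcitonin receptor, was under the floor at 0 and 24 h. Itgb3, the integrin beta 3 chain, stood just above the floor at 0 h and under it at 24 h. Among osteoclast transcription factors 9 of 21 were higher and 1 lower (median 0.79, percentile 99.78), a place this list lost without multi-transcript probe sets. Mitf was 3.73-fold and Prdm1 3.09-fold higher, and Fos differed by a factor of 1.27. The negative regulators had 0 members higher and 2 lower among 12 (median -0.46, percentile 0.98). Besides Irf8, Dusp1 was 4.45-fold lower. The list's median was 0.17 on the deposited scale, and its place was lost when probe sets were averaged. The RANK and M-CSF signalling list had 3 of 26 members higher and 2 lower (median -0.21, percentile 1.28, with 0.51 on the deposited scale). It no longer stood apart under 4 of the 10 alternatives. Traf1 was at least 9.31-fold higher and Rcan1, a target and inhibitor of calcineurin, 4.10-fold. Tnfrsf11a, which encodes RANK itself, was 1.79-fold above its 0 h level and Csf1r, the M-CSF receptor, 1.29-fold below, both within 2-fold.

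Genes of cell division stood out at 24 h. Of 36 measured cell cycle genes, 27 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.31 (percentile 100). The thymidine kinase Tk1 was 5.42-fold higher, the replication licensing factor Cdc6 5.34-fold, the helicase subunit Mcm6 4.90-fold and the cyclin Ccne2 4.70-fold. The proliferation marker Mki67 differed by a factor of 1.34 and stayed within 2-fold. Over the same interval the neutrophil and granulocyte precursor markers, which dividing marrow cells can also carry, had a median of -0.70. Cyclin-dependent kinase inhibitors and G1 cyclins did not stand apart (1 of 11 higher, 2 lower, median -0.28, percentile 6.26, and 0.45 on the deposited scale). Within it Ccnd1, cyclin D1, was 3.58-fold higher and the antiproliferative Btg2 4.31-fold lower.

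Transcripts of 2 mitochondrial energy lists were high at 24 h. Of 54 oxidative phosphorylation genes, 17 were higher and 0 lower (median 0.80, percentile 100), led by cytochrome c (Cycs, 4.30-fold), an ATP synthase subunit (Atp5g1, 4.18-fold) and Cyc1 (3.59-fold). In the tricarboxylic acid cycle 10 of 19 enzymes were higher and 0 lower (median 1.02, percentile 99.97), with Idh3a, a subunit of isocitrate dehydrogenase, 7.56-fold higher and Suclg1 4.51-fold. Glycolysis did not stand apart at 24 h (median 0.29, percentile 61.7), with Pfkp 2.31-fold higher and Pfkfb3 2.05-fold lower. Cholesterol synthesis was lower, with 5 of 18 genes lower, 1 higher and a median of -0.80 (percentile 0.01). Among these Fdft1, squalene synthase, was 3.45-fold lower, Cyp51 2.84-fold and Idi1 2.61-fold.

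Transcript lists of macrophage and immune genes were low at 24 h. Of 25 macrophage markers 19 were at least 2-fold lower and 0 higher (median -2.08, percentile 0). Over the same interval 9 of 9 megakaryocyte and platelet markers were lower, with a median of -2.02. The Fc receptors Fcgr1 and Fcgr3 were 11.8-fold and 10.7-fold lower, and the complement component C1qb 10.7-fold. The lysozymes Lyz1 and Lyz2 stayed within 2-fold at factors of 1.14 and 1.27, so this list did not move as 1 block. Lysosomal hydrolases and membrane proteins were lower in 10 of 26 and higher in 1 (median -0.86, percentile 0). Lipa, the lysosomal lipase, was 4.12-fold lower and Lgmn 2.63-fold, while the resorption enzyme Ctsk was the member that rose. Ctse was 6.36-fold lower by its brightest probe set, and another of its probe sets moved the other way. Inflammatory cytokines and chemokines were lower in 7 of 19 and higher in 0 (median -0.71, percentile 0), with Ccl6 15.3-fold lower and Ccl3 at least 7.87-fold. Interferon-stimulated genes were lower in 11 of 29 and higher in 1 (median -0.54, percentile 0.03, and 0.07 on the deposited scale), a place lost with the floor at the 60th percentile (percentile 3.05), with Ifi47 3.50-fold and Irf1 3.32-fold lower. MHC class II genes were lower in 2 of 9 (median -0.84, percentile 0.24), with H2-Aa 2.77-fold lower. In iron handling the exporter Slc40a1 was 13.6-fold lower and the heme oxygenase Hmox1 10.3-fold, but the list did not stand apart (median 0.11, percentile 37.6, and below 0 after quantile or trimmed mean scaling). With the floor at the 60th percentile it was low, with a median of -0.44 at percentile 1.28.

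**Figure D1:**
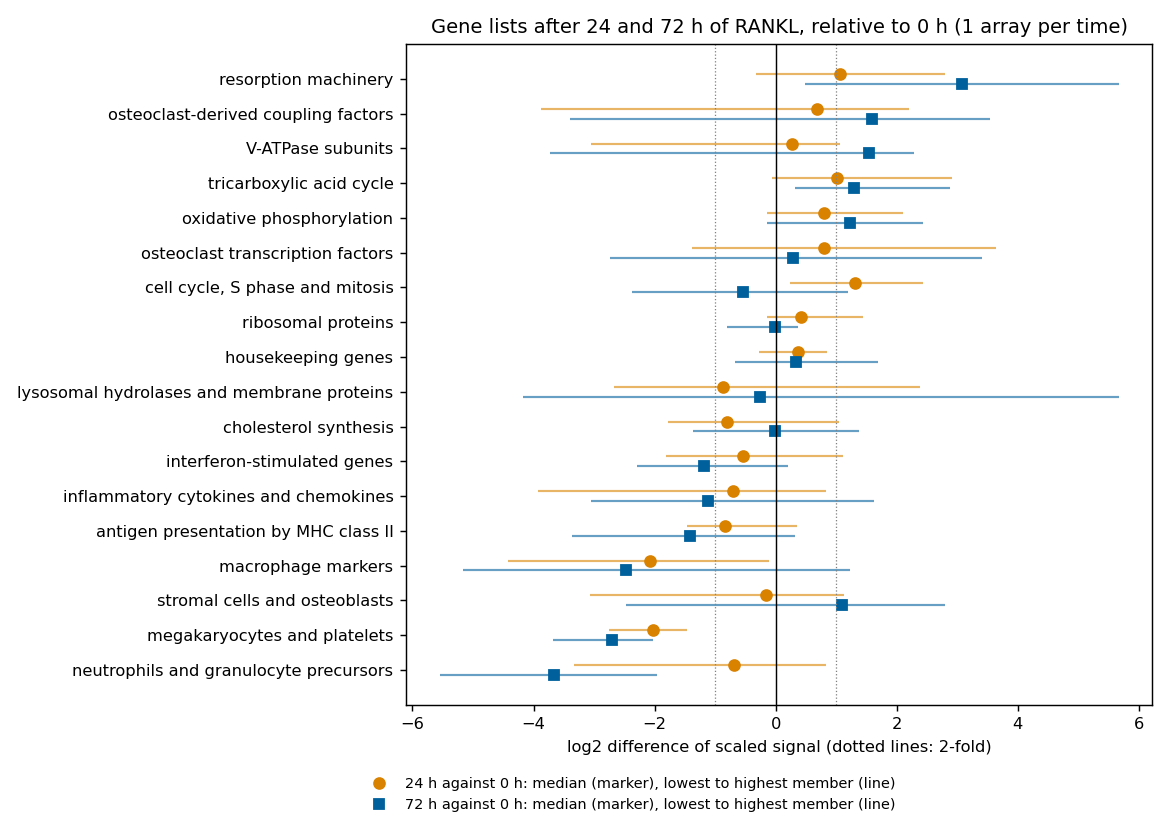
Median log2 difference of scaled signal (markers) and the lowest to highest member (lines) for 18 gene lists, at 24 h against 0 h (circles) and 72 h against 0 h (squares), 1 array per time. The resorption list moved from 1.07 to 3.07, the cell cycle list from 1.31 to -0.54 and the granulocyte list from -0.70 to -3.66; on the deposited scale the 72 h cell cycle median and the 24 h granulocyte median were above 0.

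After 72 h of RANKL, the resorption enzymes were among the brightest genes of the array. Ctsk rose 50.7-fold over 0 h, from a signal of 175 to 8856, and Mmp9, a matrix metalloproteinase of osteoclasts, 43.0-fold, from 175 to 7535. The other largest increases were those of Cyp2s1 (39.1-fold), the metal-binding protein Mt3 (33.6-fold), Cd109 (31.5-fold), the ketone body enzyme Bdh1 (27.2-fold), the motor protein Myo1d (26.9-fold) and the sodium/proton exchanger Slc9b2 (24.0-fold). From the floor, the steroid-metabolising enzyme Akr1c18 was at least 81.3-fold higher, Ocstamp higher by a log2 difference of at least 5.91, Oscar, a co-stimulatory receptor of osteoclasts, at least 45.2-fold and Rcan2 at least 31.7-fold. The largest decreases were those of Fcrls (59.9-fold), Mrc1 (35.9-fold), the acute phase protein Saa3 (35.0-fold), the chemokine receptor Cx3cr1 (34.4-fold), the scavenger receptor Stab1 (32.2-fold), the antimicrobial peptide Camp (28.1-fold), the lectin Clec10a (24.5-fold) and the transcription factor Lyl1 (21.5-fold). To the floor, Mpo (myeloperoxidase) was at least 46.7-fold lower, Ikbke at least 35.6-fold, Prtn3 at least 21.6-fold and Sorl1 at least 18.6-fold. By the 2-fold rule 1068 genes were higher and 1095 lower among 8558 measured, with 65.1 and 64.5 in simulated unchanged arrays. The higher calls made up 49.4% of all calls, and 86.8% on the deposited scale (2985 higher and 455 lower).

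Of 14 resorption genes 13 were at least 2-fold higher at 72 h and 0 lower (median 3.07, percentile 100). Besides Ctsk and Mmp9, Itgb3 was 21.0-fold higher, from a 0 h signal of 36.9 near the floor. Car2 was 19.3-fold and Acp5 9.48-fold higher, and Calcr rose from the floor at least 15.7-fold. Mmp14 was within 2-fold at a factor of 1.39. The V-ATPase, the proton pump that acidifies the resorption space, was higher in 11 of 16 subunits and lower in 1 (median 1.55, percentile 100). Its cytosolic subunits Atp6v1d and Atp6v1h were 4.90-fold and 4.82-fold higher. The exception Atp6v0a1, 1 of the alternative membrane subunits, was at least 13.2-fold lower by its brightest probe set; its others were near or under the floor. At 24 h the V-ATPase list had not stood apart (median 0.26, percentile 39.9). In the coupling factor list, signals by which osteoclasts reach bone-forming cells, 5 of 8 measured genes were higher and 1 lower (median 1.59, percentile 100, and at 24 h 0.69, percentile 90.2). Sphk1, which makes sphingosine 1-phosphate, was 11.6-fold higher and the growth factor Pdgfb 4.73-fold, while Igf1 was 10.5-fold lower. Efnb2 was at least 9.19-fold higher, with 1 of its 4 probe sets not rising. Stromal and osteoblast markers were also high in this comparison (median 1.09, percentile 100), and which cells carried the coupling factors was not tested.

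The transcription factor list no longer stood apart at 72 h (5 of 21 higher, 2 lower, median 0.29, percentile 85.8). Jdp2 remained 10.7-fold higher by its brightest probe set and Nfatc1 3.82-fold. The other Jdp2 probe set went from a signal of 7.05 to 40.4 and 45.9, but its start under the floor kept it within 2-fold, so the Jdp2 calls were lost without multi-transcript probe sets. Ppargc1b, a coactivator of mitochondrial gene expression, was 4.26-fold higher and Batf at least 6.64-fold lower. The negative regulators split, with 3 of 12 higher and 5 lower (median -0.15, percentile 33.9, and above 0 on the deposited scale). This list was low with the floor at the 20th percentile, with no floor and without multi-transcript probe sets, with medians of -0.74, -0.77 and -1.01 at percentiles 0.72, 0.84 and 0.33. Irf8 was 17.3-fold and Socs3 5.09-fold lower, whereas Id3 was 6.66-fold and the NF-kB feedback inhibitor Tnfaip3 6.42-fold higher. RANK and M-CSF signalling did not stand apart (6 of 27 higher, 3 lower, median 0.07, percentile 61.05, and below 0 after quantile or trimmed mean scaling). Tnfrsf11a was 2.40-fold higher and Csf1r differed by a factor of 1.17. Cell fusion genes did not stand apart at 24 h (median -0.17, percentile 6.42, above 0 on the deposited scale) or at 72 h (median 0.16, percentile 60.3). With probe sets averaged or multi-transcript ones left out, its 24 h median was 0.998, at percentiles of 99.7 and 99.72, so its place there depends on the probe sets. The list had no value for Dcstamp and Atp6v0d2. It had 4 of 11 members higher and 1 lower at 24 h, and 4 of 12 higher and 2 lower at 72 h. Among those that rose, Ocstamp had log2 differences of at least 3.43 and 5.91. Cd200 was 2.31-fold higher at 24 h and 12.2-fold at 72 h, and Cd44 3.99-fold and 3.24-fold. The actin ring list also lay within the range of other genes (median 0.08, percentile 42.3, below 0 after quantile or trimmed mean scaling), although Cttn, cortactin, was 5.88-fold higher and the adaptor Cbl 5.00-fold lower. At 24 h its median had been -0.06 (percentile 2.96, and 2.12 after quantile normalization, above 0 on the deposited scale and with hybridization control scaling).

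At 72 h the 2 mitochondrial energy lists were high against 0 h. Oxidative phosphorylation was higher in 31 of 54 genes and lower in 0 (median 1.22, percentile 100), with Cycs 5.40-fold and Cyc1 4.79-fold higher. In the tricarboxylic acid cycle 14 of 19 enzymes were higher and 0 lower (median 1.30, percentile 100), with Idh3a 7.36-fold, Suclg1 6.85-fold and Pdhb, a pyruvate dehydrogenase subunit, 4.96-fold higher. Glycolysis had a median of 0.47 (percentile 95.5, and 98.5 with probe sets averaged or 98.2 with unmatched lists), with 3 of 17 genes higher and 1 lower. Iron handling did not stand apart (5 of 12 higher, 4 lower, median -0.12, percentile 27.0, and above 0 on the deposited scale) because its members went both ways. The metalloreductase Steap4 was at least 22.4-fold higher, while Slc40a1 was 8.76-fold and the phagosomal metal transporter Slc11a1 7.12-fold lower. Cholesterol synthesis was back among other genes (median -0.01, percentile 50.6, and 0.76 on the deposited scale).

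The loss of macrophage and immune genes persisted at 72 h. Macrophage markers were lower in 18 of 25 and higher in 1 (median -2.47, percentile 0). The member that rose was Cd68, a lysosomal membrane protein also found in osteoclasts, whose log2 difference was 1.22. Lyz1 and Lyz2 stayed within 2-fold. Lysosomal genes were lower in 9 of 26 and higher in 2 (median -0.27, percentile 0.33), with Ctsh 6.02-fold and Lamp1 5.15-fold lower. That median was 0.51 on the deposited scale, and the list no longer stood apart from unmatched random lists. Interferon-stimulated genes were lower in 17 of 29 and higher in 0 (median -1.18, percentile 0), with Bst2 4.91-fold and Ifi47 4.76-fold lower. MHC class II genes were lower in 6 of 10 and higher in 0 (median -1.41, percentile 0), with H2-Aa 10.3-fold and H2-DMa 6.07-fold lower. Inflammatory cytokines and chemokines were lower in 10 of 18 and higher in 3 (median -1.12, percentile 0), with Il1b 6.73-fold lower and Ccl9 at a factor of 1.94 above its 0 h level, within 2-fold. Over the same times the megakaryocyte and granulocyte markers were lower and several collagen genes higher.

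**Figure D2:**
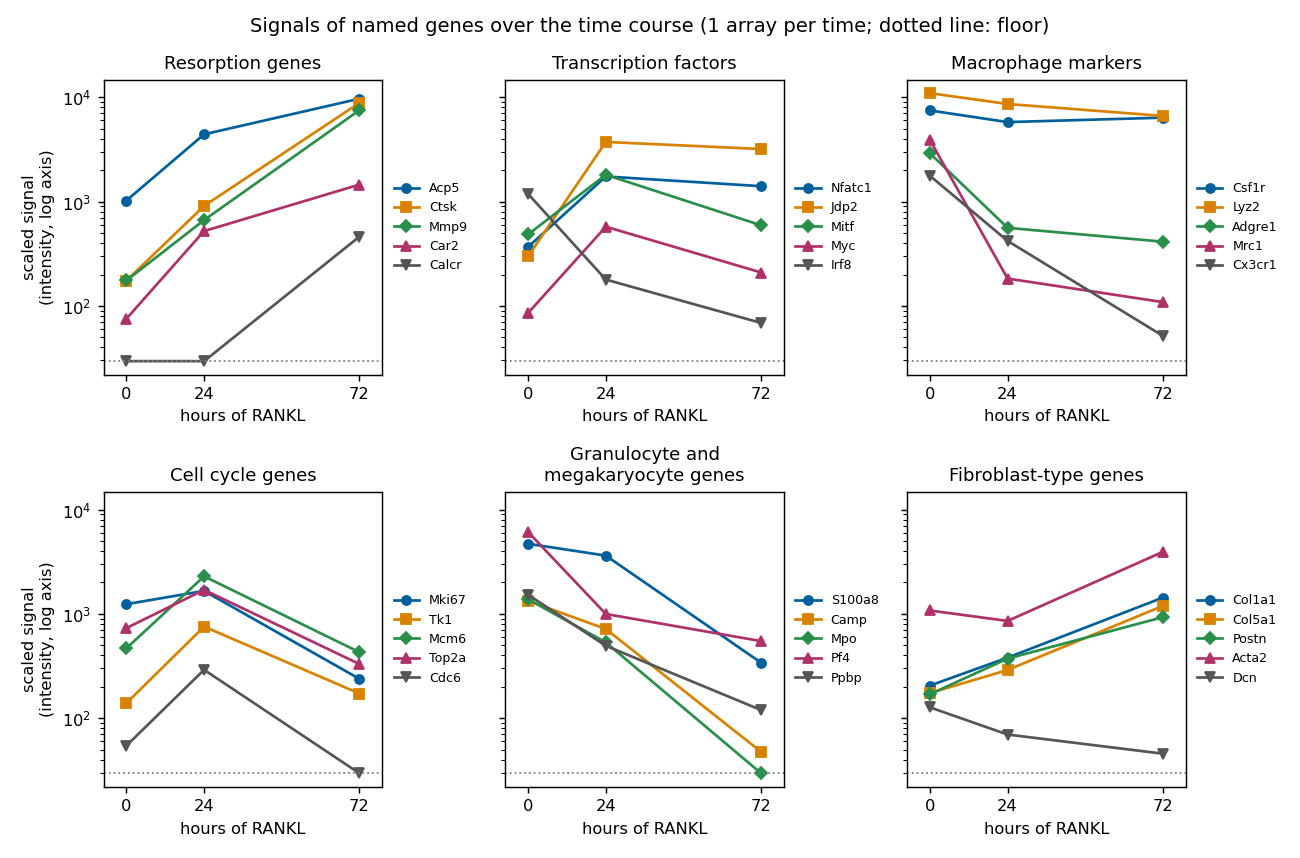
Scaled signal (intensity, log axis) of 30 genes at 0, 24 and 72 h of RANKL, 1 array per time, with values under the floor of 29.6 drawn at the floor. Ctsk climbed from 175 to 8856 and Mki67 ended at 238 after 1660 at 24 h.

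Between 24 and 72 h, the resorption list was high and the cell cycle list low. Mt3 was 42.9-fold higher at 72 h than at 24 h, Oscar 26.3-fold, Akr1c18 23.3-fold, Rcan2 22.1-fold and the vesicle GTPase Rab38 15.4-fold. From the floor, Itgb3 was at least 26.2-fold and the granzyme Gzmd at least 25.9-fold higher. The largest decreases were those of Camp (15.1-fold), the membrane protein Ifitm1 (14.1-fold), the iron-binding lipocalin Lcn2 (11.6-fold), the calcium-binding S100a8 (10.7-fold) and Slc6a4 (10.7-fold), and Mpo (18.0-fold) and Cdc6 (9.84-fold) fell at least that far to the floor. In total 581 genes were higher and 839 lower among 8391 measured, with 64.5 and 64.4 in simulated unchanged arrays. Higher calls made up 40.9% of the total, and 30.8% after scaling to the hybridization controls (489 higher and 1101 lower). This comparison leaves out the 0 h array, the dimmest of the 3.

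Of 36 cell cycle genes 34 were at least 2-fold lower at 72 h than at 24 h and 0 higher (median -1.93, percentile 0), with Mki67 6.98-fold, Mcm6 5.35-fold and the topoisomerase Top2a 5.15-fold lower. Against 0 h the list was also low at 72 h (median -0.54, percentile 0.06, and 0.23 on the deposited scale), with 8 of 36 members lower and 1 higher. Over the same interval the granulocyte list, whose median fell by 3.03, dropped too. Ccnd1 was 2.86-fold lower and Ccnd2, cyclin D2, 4.91-fold higher, in a list of kinase inhibitors and G1 cyclins that did not stand apart (median -0.12, percentile 61.2, above 0 after quantile normalization; against 0 h -0.35, percentile 15.1, and 1.93 with no floor, above 0 on the deposited scale). The resorption list gained 11 of 14 members (median 1.69, percentile 100) and the V-ATPase list 9 of 16 (median 1.08, percentile 100), with 0 lower in either. Cholesterol synthesis gained 4 of 18 (median 0.74, percentile 100), with Msmo1 2.71-fold higher. Oxidative phosphorylation had 0 of 54 members past 2-fold, but its median of 0.30 was at percentile 100, and the tricarboxylic acid cycle had 2 of 19 higher (median 0.51, percentile 99.98). Iron handling stood apart (4 of 12 higher, 1 lower, median 0.35, percentile 98.9), with Steap4 15.3-fold higher and the transferrin receptor Tfrc 2.42-fold by its brightest probe set, the lowest of its values, the 2 others having log2 differences of 3.11 and 4.04. Coupling factors did too (2 of 8 higher, 0 lower, median 0.51, percentile 98.6), except without multi-transcript probe sets. Lysosomal genes had a median of 0.28 (percentile 99.6, 4 of 26 higher and 5 lower), with Hexa 2.83-fold and Cd68 2.75-fold higher, and this place was lost without multi-transcript probe sets. Interferon-stimulated genes fell further (7 of 25 lower, 0 higher, median -0.49, percentile 1.36), with Bst2 3.97-fold lower.

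Several lists did not move past their matched random lists between 24 and 72 h. Macrophage markers had a median of -0.04 (percentile 73.6), with 3 of 23 lower and 1 higher, and the sign of that median changed with quantile, trimmed mean or no scaling. Among them Cx3cr1 was still 8.15-fold lower. For MHC class II the median was -0.57 (percentile 3.14, and 2.35 with probe sets averaged), for inflammatory genes 0.08 (percentile 85.5, below 0 with hybridization control scaling, but high with the other 3 floors or without multi-transcript probe sets, up to 0.61 at percentile 99.96) and for glycolysis -0.03 (percentile 71.6, above 0 with quantile, trimmed mean or no scaling). Transcription factors had 7 of 21 lower and 0 higher (median -0.29, percentile 16.8), among them Mitf (3.05-fold), Junb (2.91-fold), Myc (2.75-fold) and Fos (2.04-fold). The Fos call was lost under 2 of the other scalings. Negative regulators had 4 of 12 higher and 2 lower (median 0.14, percentile 92.4, and 98.6 with the floor at the 60th percentile), with Id3 9.55-fold higher. The RANK signalling list had a median of 0.06 (percentile 92.9, but 99.55 with probe sets averaged and 97.7 without multi-transcript ones) and the fusion list 0.13 (percentile 86.1), both below 0 with hybridization control scaling. The actin list had a median of 0.17 (percentile 96.5, and 98.0 with unmatched lists), with Cttn 4.41-fold higher and the GTPase Rac2 4.06-fold.

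Time courses were sorted by the 2-fold rule in the intervals from 0 to 24 h and from 24 to 72 h. Here "only" means within 2-fold in the other interval, so a gene higher by 24 h only can still be high at 72 h. By this sorting, 725 genes were higher by 24 h only, 448 higher after 24 h only, 54 higher in both intervals and 333 higher and then lower. A further 624 were lower by 24 h only, 431 lower after 24 h only, 75 lower in both intervals and 79 lower and then higher, while 5976 stayed within 2-fold in both intervals. Simulated unchanged arrays gave 55.9 genes higher by 24 h only, 57.0 higher after 24 h only and 8.15 higher and then lower. Both comparisons with 0 h share that array. Of 1098 genes higher at 24 h and measured in both, 473 were also higher at 72 h, where independent lists would share 134 and unchanged arrays shared 7.70. Of 778 genes lower at 24 h, 594 were also lower at 72 h, with 103 and 8.24 as the corresponding values. Part of each excess can come from the shared 0 h array.

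Markers of other cell types moved in 3 ways. Megakaryocyte and platelet markers were lower in 9 of 9 at 24 h (median -2.02, percentile 0) and in 9 of 9 at 72 h (median -2.71, percentile 0), with little further change after 24 h (1 of 8 lower, median -0.61, percentile 5.95, and 1.05 with probe sets averaged). Pf4, platelet factor 4, had a signal of 6085 at 0 h and was 6.10-fold lower at 24 h and 11.1-fold lower at 72 h. Neutrophil and granulocyte precursor markers were lower in 4 of 12 at 24 h (median -0.70, percentile 0.05, and 0.03 on the deposited scale) and in 12 of 12 at 72 h (median -3.66, percentile 0). From 24 to 72 h, 11 of 12 were lower (median -3.03, percentile 0). S100a8 fell from 3618 to 339 in that interval. Stromal and osteoblast markers did not stand apart at 24 h (median -0.16, percentile 9.44, above 0 on the deposited scale). At 72 h 8 of 16 were higher and 2 lower against 0 h (median 1.09, percentile 100), and 9 of 15 were higher and 0 lower against 24 h (median 1.32, percentile 100). Against 0 h Col1a1 and Col5a1, collagen chains of fibroblasts, were 6.98-fold and 6.86-fold higher and the matrix protein Postn 5.49-fold. The Col1a1 value is that of its brightest probe set, and its other probe set had a log2 difference of 0.60, within 2-fold. Vcam1 was 5.57-fold lower by its brightest probe set, with another of its probe sets moving the other way. The collagen-binding Dcn had a log2 difference of -1.48.

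The remaining cell types were scarcely detected. Of 11 B cell genes 5 were measured against 0 h (medians -0.08 and -0.61, percentiles 42.9 and 6.12), and of 12 T and NK cell genes 4 (medians -0.10 and -0.12, percentiles 44.8 and 33.1). Erythroid markers had 3 measured (medians 0.19 and -0.47, percentiles 75.8 and 17.3), endothelial markers 4 and 5 (medians -0.42 and -0.08, percentiles 16.2 and 42.3) and dendritic cell markers 5 and 6 (medians -0.14 and 0.15, percentiles 27.5 and 73.3), each at 24 and 72 h. Of these medians, those between -0.42 and -0.08 were above 0 on the deposited scale. Mast cell and basophil markers had 3 measured at 72 h (median 0.10, percentile 61.4, below 0 after trimmed mean scaling). Adipocyte markers had 2 measured, too few for a median. From 24 to 72 h the B cell, mast cell, endothelial and dendritic lists had medians of -0.19, 0.55, 0.43 and 0.32, at percentiles 35.3, 90.1, 90.7 and 89.2.

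Housekeeping genes and spiked controls bear on how far the arrays can be compared. Housekeeping genes did not stand apart at 24 h (0 of 11 past 2-fold, median 0.37, percentile 57.5), at 72 h (2 of 11 higher, median 0.34, percentile 64.4) or between them (median -0.24, percentile 21.9). Actb, beta-actin, differed by factors of 1.10 and 1.08 from 0 h. The members that rose at 72 h were Tfrc (3.21-fold) and Sdha (2.09-fold). Ribosomal protein genes did not stand apart from 0 h at 24 h (median 0.41, percentile 75.4, but 98.4 without multi-transcript probe sets) or 72 h (median -0.01, percentile 9.04, and 0.76 on the deposited scale), but were lower between 24 and 72 h (2 of 24 lower, median -0.44, percentile 0.35), a place lost without multi-transcript probe sets and with unmatched lists. Relative to the gene median, the 18 hybridization control probe sets had median log2 differences of -0.07 at 24 h (SD 0.22) and 0.05 at 72 h (SD 0.19). The 24 poly-A control probe sets, bacterial transcripts that can be added to the RNA before labelling, were lower in 24 of 24 at both times, with medians of -1.48 at 24 h (SD 0.40) and -0.73 at 72 h (SD 0.26). The floor was not applied to control probe sets, and several poly-A ones were under it at 24 h. The brightest of them went from a signal of 669 at 0 h to 279 at 24 h and 410 at 72 h. The labels do not state whether the poly-A controls were added in equal amounts, or whether the 3 RNAs came from 1 marrow preparation. Scaling to the poly-A controls was not run. Had they been added equally, it would raise every difference from 0 h by about the size of the poly-A medians above. Low medians such as that of lysosomal genes at 24 h (-0.86) or the cell cycle at 72 h (-0.54) would then lie above 0. Macrophage markers at 24 h (-2.08) would stay below 0. For Gapdh the 3′, middle and 5′ control probe sets differed from 0 h by 0.50, 0.67 and 0.79 at 24 h and by 0.10, 0.39 and 0.76 at 72 h. Those of beta-actin differed by -0.18, -0.01 and 0.03 at 24 h and by -0.25, 0.07 and 0.16 at 72 h. In both genes the 3′ value was the lowest at both times. From 24 to 72 h those of Gapdh differed by -0.40, -0.29 and -0.02, in the same order. Those of beta-actin differed by -0.07, 0.08 and 0.14, so the 3′ value was again the lowest. Such differences along a transcript bear on RNA quality, so a difference in quality among the 3 arrays, 24 and 72 h included, is not excluded.

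**Figure D3:**
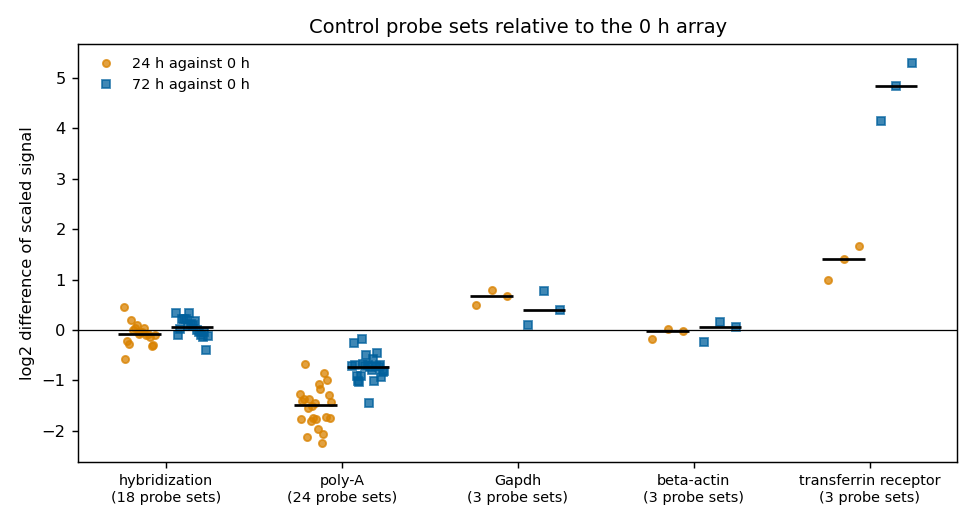
Log2 difference of scaled signal from the 0 h array for each control probe set (points) and the median of each kind (bars), at 24 h (circles) and 72 h (squares). The hybridization controls lie around 0, the poly-A controls around -1.48 and -0.73, and the transferrin receptor probe sets at 72 h between 4.14 and 5.29. The floor was not applied to control probe sets, and the 5′ and middle transferrin receptor probe sets were under it at 0 h (20.1 and 14.4).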

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

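All tests below were chosen after the main results were seen, and those on granulocyte precursors as the source of the cell cycle change and on dilution of all other cell types also used values already seen.

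The cell cycle list moved in opposite directions against 0 h, with a median log2 difference of 1.31 at 24 h and -0.54 at 72 h; this difference was not tested, as there is 1 array per time. Scaling of the arrays as the whole cause of the rise was examined with the 3 other common scalings. Their lowest median at 24 h was 1.11, at percentile 100. Trimmed mean and hybridization control scaling move all genes of an array alike by a small amount. They could hardly have removed the rise or changed the percentile. The list kept its place after quantile normalization, which is not such a shift. These values show only that the rise does not depend on the choice among these scalings. As to a higher share of granulocyte precursors at 24 h, the granulocyte list had a median of -0.70, and 0.03 on the deposited scale. It showed no 2-fold rise on either scale. The check was set after the median was known, so it does not test this explanation independently. For the later fall, a loss of dividing granulocyte precursors cannot be told apart from slower division of the macrophage lineage, since the granulocyte list dropped by 3.03 over the same interval without an earlier rise. Withdrawal from the cell cycle during differentiation under RANKL stays open as a biological explanation and was not tested.

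Collagen and other fibroblast genes were higher at 72 h. A single aberrant probe set per gene is argued against, as the 6 other probe sets of 5 of the 8 stromal genes that rose had a median log2 difference of 2.14. Of these 6, 5 were at least 2-fold higher, and the exception was the other probe set of Col1a1, at 0.60. The other probe set of Acta2 is not among the 6. It was under the floor on all 3 arrays, so it gave no fold and did not bear out the rise of Acta2. More fibroblast-like cells in the 72 h culture is a candidate explanation. A second list of fibroblast genes, fixed before its values were seen, had a median of 1.75 at 72 h against 0 h with 22 of 26 members higher, and 0.00 at 24 h with 2 of 24 higher. Against it, the other 4 of that list stayed within 2-fold (Fap -0.30, Mgp -0.24, Pdgfra 0.25, Timp3 0.84), as did Lum (-0.54), and Dcn was lower (-1.48), and expression of these genes by the macrophage lineage itself was not tested.

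Granulocyte genes fell from 24 to 72 h and megakaryocyte genes by 24 h. Dilution of all other cell types alike would lower their lists alike. The granulocyte, megakaryocyte and stromal medians at 24 h were -0.70, -2.02 and -0.16, spanning 1.85, so these lists did not fall alike. The medians were known when the check was set, so it does not test dilution independently. Loss of granulocyte-lineage cells may account for the first, as a second granulocyte list had a median of -1.12 from 24 to 72 h, though from 4 measured genes with Fpr2 at 0.06, and since that list was already at -1.28 at 24 h against 0 h (5 of 8 lower), when such a loss began stays open. Loss of megakaryocytes or platelets by 24 h may account for the other, as a second megakaryocyte list had a median of -1.39 with 8 of 11 members lower and 1, Gng11, higher. Lower expression within cells that remained, under RANKL or with time in culture, was not tested.

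Among the control probe sets, which entered no comparison of genes, the 3 for the transferrin receptor were above their 0 h level at 72 h, with log2 differences of 4.14 (3′), 4.84 (5′) and 5.29 (middle). The floor was not applied to control probe sets. The 5′ and middle ones had 0 h signals of 20.1 and 14.4, under the floor of 29.6, so the sizes of their differences are uncertain. In the same comparison the 3 gene probe sets of Tfrc differed by 1.68, 4.07 and 5.04, and the brightest, used for the gene, gave the lowest of these.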

How the results depend on the processing

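The deposited scale, hybridization control scaling and trimmed mean scaling were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because each time has 1 array and no result comes from a test. Of 42 list medians that stood apart, 34 did so under each of their 10 alternatives and 8 were lost under at least 1. Of the 48 that did not stand apart, 13 did so under at least 1 alternative. Of 77 called differences of genes named for their size or in advance, 71 kept their call wherever the gene had a value; the others were Tufm (probe sets averaged), Malat1 at 24 h and Jdp2 at both times (multi-transcript probe sets left out), Fos and Irf8 (72 h against 24 h). Leaving out multi-transcript probe sets gave no value for genes with no other probe set. Many of these genes were picked for the size of their change, so their kept calls say little about calls near 2-fold. Signal over background limits genes near the floor, and the counts depend on where it lies.

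In the order 24 h against 0 h, 72 h against 0 h and 72 h against 24 h, the counts were 1112 higher and 778 lower, 1068 and 1095, and 581 and 839. The time courses held 725 genes higher by 24 h only, 448 higher after 24 h only, 333 higher then lower, 624 lower by 24 h only and 431 lower after 24 h only. Quantile normalization, trimmed mean scaling, hybridization control scaling, averaged probe sets and leaving out multi-transcript probe sets kept each of these within 1.5 times. The shifts beyond that with a floor or a threshold follow from the construction of those settings, which admit more or fewer genes.

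With no floor, the 3 comparisons gave 2004 higher and 1869 lower, 1971 and 2252, and 1469 and 1859, and the 5 time courses 1204, 767, 662, 1079 and 971. With the floor at the 20th percentile, 1307 genes were lower at 24 h and 1659 at 72 h against 0 h, 981 were higher and 1267 lower from 24 to 72 h, 957 were lower by 24 h only and 705 lower after 24 h only. At the 60th percentile, 712 were lower at 72 h against 0 h, 364 higher from 24 to 72 h, 292 higher after 24 h only and 262 lower after 24 h only. A 1.5-fold threshold gave 2255 higher and 1499 lower, 1986 and 1997, and 1193 and 2032, with 685 higher after 24 h only, 983 higher then lower, 944 lower by 24 h only and 795 lower after 24 h only. A 3-fold threshold gave 356 and 361, 461 and 511, and 225 and 238, with time courses of 282, 201, 63, 337 and 164.

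On the deposited scale, 3302 genes were higher and 314 lower at 24 h, 2985 and 455 at 72 h against 0 h, with 2584 higher by 24 h only, 566 higher then lower, 253 lower by 24 h only and 211 lower after 24 h only. The median shift of 0.73 and 0.77 between these arrays adds to every gene. On that scale 6 list medians that stood apart changed sign: at 24 h those of the negative regulators (0.17), RANK and M-CSF signalling (0.51), interferon-stimulated genes (0.0702) and granulocyte markers (0.0326), and at 72 h against 0 h those of lysosomal genes (0.51) and the cell cycle (0.23). In each case the percentile among random lists stayed at or under 2.5, as such a shift moves the random lists too and could hardly change it.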

Other observations

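Gene groups beyond the fixed lists were also described, on lists chosen after the main results were seen. Of 74 mitochondrial ribosomal protein genes, 36 were at least 2-fold higher at 24 h and 0 lower (median log2 difference 0.94, percentile 100), and 26 were higher at 72 h (median 0.84, percentile 100). Of 20 measured genes of the mitochondrial import machinery, 10 were higher at 24 h and 0 lower (median 1.06, percentile 100), led by Timm8a1 (2.20) and Timm17a (1.74). Fatty acid oxidation had 0 of 16 genes past 2-fold at 24 h (median 0.26, percentile 51.2) and 6 higher at 72 h (median 0.67, percentile 99.0), but did not stand apart between 24 and 72 h (4 higher, median 0.20, percentile 96.55).

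Several growth-related groups were high at 24 h. In serine and one-carbon metabolism, which feeds nucleotide synthesis, 4 of 7 measured genes were higher at 24 h (median 1.31, percentile 99.8), with Shmt1 at 2.45 and Shmt2 at 1.82, and the list was lower from 24 to 72 h (median -0.93, percentile 1.22). Phgdh, the entry enzyme of serine synthesis, went the other way, at 0.08 at 24 h and 1.44 at 72 h. The 8 subunits of the TRiC chaperonin, which folds actin and tubulin, had 4 higher at 24 h (median 1.02, percentile 99.5) and a median of -0.75 from 24 to 72 h (percentile 0.18). Proteasome subunits were higher in 13 of 37 at 24 h (median 0.70, percentile 99.7) and had a median of 0.30 at 72 h against 0 h (percentile 83.3) and of -0.39 from 24 to 72 h (percentile 0.92). Cytosolic aminoacyl-tRNA synthetases were higher in 5 of 18 at 24 h (median 0.65, percentile 97.6) and in 4 at 72 h (median 0.61, percentile 98.9).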
